A study of Aspergillus oryzae RIB40 with 32 samples.

How the data were processed

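Per the labels' protocols, Aspergillus oryzae RIB40 was grown in 2 consecutive batch cultivations on glucose at 30 °C and pH 3.5, and the mycelium was moved to shake flasks with glucose or 1 of 10 inducers. It was harvested after 2 h, and total RNA was labelled with Cy3 for 1-colour hybridisation to custom Agilent arrays. Each of the 32 files holds 1 array. Samples were grouped by the substrate named in the labels, with 3 arrays for each inducer and 2 for glucose.

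Per the file headers, the scanner files were made with Agilent Feature Extraction 10.5.1.1 and hold spot intensities on a linear scale, among them a processed signal that is already background-corrected, a median signal and a local background. Besides these, the authors deposited for each inducer a table of log2 fold changes against the glucose control per probe. The p-values in the deposited tables come from the authors' own test, whose columns are those of limma, per the file headers; the normalization behind them is not given in the sources used here. No fold or p-value of these tables enters the results below except where the authors' deposited tables are named, and folds there had correlations of 0.830 to 0.920 across genes with those computed here.

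The array holds 36144 probes for 12049 genes, of which 12046 have 3 probes. All 12049 identifiers matched a locus tag of the RefSeq gene table of A. oryzae RIB40 (assembly ASM18445v3), which gave 714 symbols; the pairing of probes with genes and the product names come from the authors' deposited tables, where 6658 genes are named predicted protein only. The build behind the array is not given in the sources used here, so that no coordinates are given, and which genes neighbour each other was taken from the order in that table. The 1417 control spots per array and spots marked as nonuniform or as population outliers were left out. The log2 processed signal minus the array's 75th percentile was averaged over a gene's probes. A gene was tested if at least 1 of its probes was well above background on all arrays of at least 1 group. Where all probes of a gene were below that level on every array of the dimmer group, the change is a bound: the brighter group's mean is set against the higher of the lowest signal well above background and the gene's own.

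Tests were made with limma 3.58.1 in R 4.3.3, with the data.table package, version 1.17.8, for reading. A linear model with 11 groups was fitted to all 32 arrays, so that the spread of each gene is shared between groups, and moderated tests were adjusted by Benjamini-Hochberg within each comparison at a threshold of 0.05. Each inducer was compared with glucose and with the mean of the other 9 inducers, 8 pairs of related inducers were compared directly, and an F test asked for any difference among the 10 inducers. Intervals of pair differences are 95% intervals from the same fit. These comparisons, the settings tried, the gene lists and the rule for named genes were set before the data were examined.

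Gene lists were drawn by words in product names and symbols: starch, cellulose, xylan, arabinan, mannan and galactoside, xyloglucan and pectin enzymes and their union, cell wall enzymes, sugar transporters, pentose catabolism, glycolysis, gluconeogenesis with the glyoxylate shunt and acetate use, citric acid cycle, cytosolic ribosomal proteins, protein folding and secretion, heat shock and oxidative stress, proteases, secondary metabolism, amino acid and nitrogen transport and use, conidiation markers and carbon regulators. Names can take in genes of other functions. Lists of at least 5 tested genes were tested with camera at its preset correlation of 0.01 between genes, and again with the correlation estimated from the data, adjusted over all lists and comparisons of the same kind. The enzyme union shares its members with its parts. Of the carbon regulators searched for by symbol, 2 were on the array under those names.

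Genes were named by a fixed rule. Against glucose it took the 10 largest rises and 10 largest falls among genes that passed, with every array of the inducer on the same side of both glucose arrays. Against the other inducers it took 5 and 5, with every array on the same side of the other 9 group means, and in pairs 3 and 3 whose arrays did not overlap. From each list with members that passed it took the 2 largest rises and 2 largest falls, and it took the carbon regulators always. The text gives values for the highest ranked and for genes named in several comparisons; genes without a product name are given only by identifier, at most 2 rising and 2 falling per comparison. Ranges over all inducers are given for genes that the rule names on at least 1 of them.

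The arrays came on 8 slides of 4 in the order of the sample names, so that each slide holds neighbouring inducers and the glucose arrays share a slide with 1,3:1,4-beta-Glucohexaose alone. The slide was tried as a random block for all comparisons, as a fixed block where slides are linked by a shared inducer, and within the slide that held both groups. Other settings were quantile normalization, normexp background correction with an offset of 50, no filter and a stricter filter on dim genes, the brightest probe or the median of probes, keeping the outlier spots, the flask number as a block, only the groups compared, a trended and robust prior, a 2-fold limit and leaving out each array in turn. The normexp setting used the median signal, because the files hold no mean signal. The within-slide fits of 2 pairs, the omission of Xyloglucan 1 and D-Xylopentaose 1 and that of each inducer in turn from the mean of the others were chosen after the data were seen. Left with 1 glucose array, the fit assumes that it varies like the other groups.

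The procedure was tested on simulated values of 11524 genes made from the real means and spreads. For 1,3:1,4-beta-Glucohexaose against glucose it recovered 2.99% of 67 genes changed 1.5-fold, 35.8% of 67 changed 2-fold and 81.8% of 66 changed 4-fold, and it called 4 of 11324 unchanged genes. For Mannohexaose against the other inducers the shares were 37.3%, 71.6% and 89.4%, and for Cellohexaose against Sophorose 16.4%, 32.8% and 86.4%.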

Results

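Transcripts were measured in mycelium of Aspergillus oryzae RIB40, a filamentous fungus used in food fermentation and enzyme production, after 2 h on glucose or on 1 of 10 di- and oligosaccharides. The question, as the series states it, is which part of the transcriptome responds to sugars derived from plant biomass. The inducers were 1,3:1,4-beta-Glucohexaose, Glc-Maltotriosyl-maltotriose, D-Xylopentaose, 1,5-alpha-L-Arabinoheptaose, Galactosyl-mannotriose, Sophorose, Turanose, Mannohexaose, Cellohexaose and Xyloglucan. Each inducer had 3 shake flasks and glucose had 2, so that 32 arrays were compared. According to the labels each flask was a separate culture, and the mycelium for the flasks came from 2 consecutive bioreactor cultivations at 30 °C and pH 3.5. No flask is tied to either cultivation, so cultivation and inducer cannot be told apart, and the p-values below measure the spread between flasks.

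The 75th percentile of the processed signal ran from 255 on the array of Mannohexaose 3 to 3683 on that of glucose 2. The share of probes well above background ran from 72.6% on Mannohexaose 3 to 99.2% on Xyloglucan 1. No spot was saturated, and no 2 arrays held identical values. Of 12049 genes, 11524 were above background on all arrays of at least 1 group and were tested. Changes are given on the log2 scale with n = 3 for each inducer and n = 2 for glucose, and the number of arrays limits their precision. The first principal component held 34.7% of the variance and the second 23.1%. On the second, the 15 arrays of 1,3:1,4-beta-Glucohexaose, Glc-Maltotriosyl-maltotriose, D-Xylopentaose, 1,5-alpha-L-Arabinoheptaose and Galactosyl-mannotriose lay between 8.1 and 45.1, and the 15 of the other 5 inducers between -48.7 and 1.9. Xyloglucan 1 and D-Xylopentaose 1 stood apart from their groups.

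**Figure D1:**
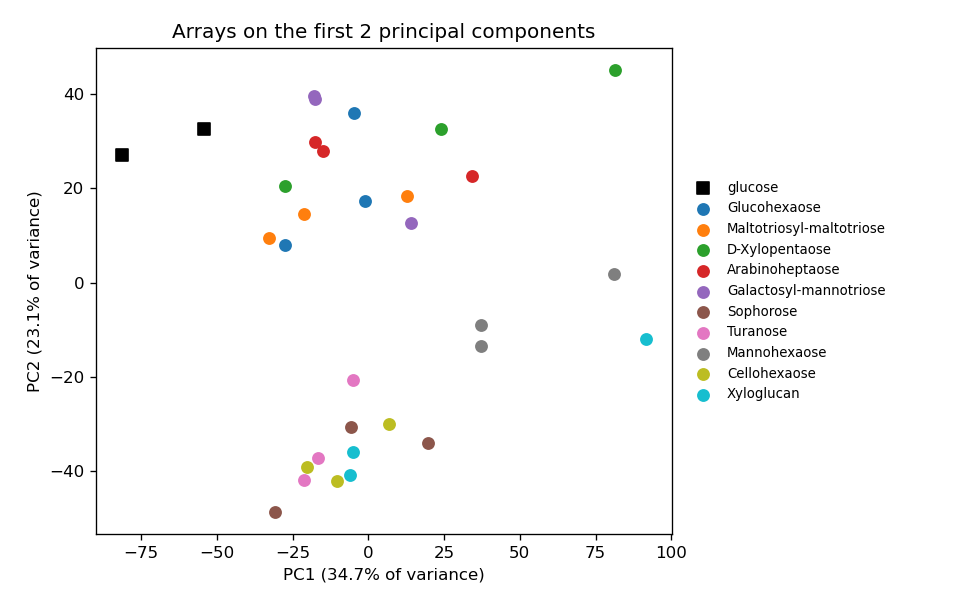
Each point is 1 array, placed by its scores on the first (x, 34.7% of variance) and second (y, 23.1%) principal components of the log2 signals and coloured by carbon source. Glucose lay at 27.2 and 32.5 on the second component, and the arrays of Sophorose, Turanose, Mannohexaose, Cellohexaose and Xyloglucan lay at 1.9 or below.

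Some of the largest changes against glucose were found on every inducer. AO090005000962, a transporter of the major facilitator superfamily, rose by 7.34 to 8.57, and a second such transporter, AO090012000001, by 6.42 to 7.61. A proton-coupled oligopeptide symporter, AO090010000743, rose by 5.27 to 7.29. Its neighbour on the array's gene numbering, the sulfatase AO090010000744, fell on all 10, with values from -2.76 to -5.44 on 9 inducers and at least 12.4-fold lower on Mannohexaose, where the gene was not well above background. Isocitrate lyase (AO090009000219), which opens the glyoxylate shunt, rose by 3.38 to 4.58. The flavin-dependent oxidoreductase AO090038000132 fell on all 10 inducers, with values from -3.10 to -5.39. In limma, 1249 genes rose and 414 fell on all 10 inducers (816 and 544 after quantile normalization, 87 and 29 after normexp correction), and 8816 changed on at least 1. Independent lists of the same sizes would share 0.00797 rising and 3.52e-05 falling genes. At an unadjusted p under 0.05, 1499 rose and 583 fell on all 10. Unchanged groups simulated against the same 2 glucose arrays gave 3.45 and 4.4, but hold no effect of slide 1, which these arrays share.

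The fold changes against glucose had a median correlation across genes of 0.829 over the 45 pairs of inducers, with a range of 0.702 to 0.975; genes are not independent replicates. Unchanged groups simulated against shared glucose arrays gave 0.600. The median covariance was 0.814 against a simulated 0.0874. In 55.4% of genes the sign was the same on all 10 inducers, against 25.6% in the simulation. When the inducers of a pair were set against different glucose arrays, a split chosen after the data were seen that leaves 1 array to each, the medians were 0.718 for the correlation and 0.752 for the covariance. Without glucose 1, 1067 genes changed in the same direction on all inducers, against 1663 with it.

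The lowest count against glucose was 3514 genes (Glc-Maltotriosyl-maltotriose) and the highest 6179 (Mannohexaose). The median log2 change of all genes lay between 0.10 and 0.34, and changes of gene groups are read against it. After quantile normalization this median lay between -0.10 and -0.08, and the share of rising genes fell to between 44.2% and 49.2%. After normexp background correction it lay between -0.81 and 0.17 (-0.47 and 0.54 against the other inducers), between 360 and 1290 genes passed, 222 of the 485 values of named genes kept direction and call, and 28 turned relative to all genes. The authors' deposited tables called 726 to 3931 probes, counted here as 184 to 1240 genes. Of the genes passing here, 1813 to 3922 changed at least 2-fold. 1,3:1,4-beta-Glucohexaose is the 1 inducer with arrays on the slide that held glucose, where within that slide 2428 genes rose and 858 fell. For Cellohexaose, linked to glucose through 2 slides, 2995 genes passed with the slide as a fixed block. For the other inducers slide and glucose comparison cannot be told apart.

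Enzymes that release sugars from plant polysaccharides were higher as a group on every inducer by camera at its preset correlation (adjusted p = 1.55e-05 on Turanose to 0.0122 on Galactosyl-mannotriose; adjusted p = 0.399 to 0.615 with an estimated correlation). Of 88 tested members, 29 to 58 rose and 0 to 8 fell (29 to 59 and 0 to 8 when adjusted over the list alone), with median log2 changes of 0.54 to 1.29. AO090038000223 and AO090009000356, beta-glucosidases that release glucose from short beta-glucans, rose by 2.75 to 3.84 and 3.13 to 3.87. The cellobiohydrolase gene cbhC (AO090038000439) rose by 1.81 to 3.18. The beta-xylosidase AO090701000838 rose by 2.04 to 2.62, and the pectate lyase AO090011000673 by 1.03 to 2.16; relative to all genes cbhC and AO090011000673 turned on 5 and 8 inducers after normexp correction. After normexp correction the list was called on 1 inducer, and its median relative to all genes ran from -0.39 to 0.08, so that its direction turned on some inducers; after quantile normalization it was called on 9. With the slide as a block its median was 0.67 on 1,3:1,4-beta-Glucohexaose and 1.11 on Cellohexaose, and within slide 1 it was 0.67 on 1,3:1,4-beta-Glucohexaose.

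**Figure D2:**
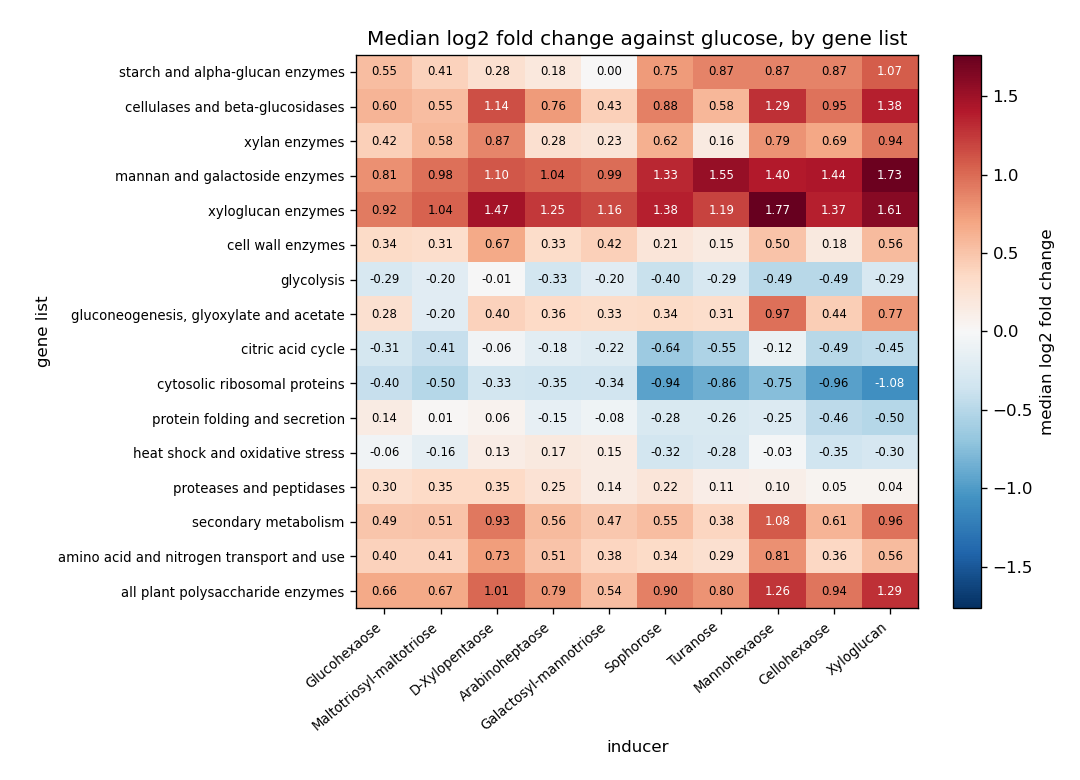
Each cell gives the median log2 fold change against glucose of 1 gene list (y) on 1 inducer (x), with red for higher and blue for lower than glucose. Ribosomal proteins lay between -1.08 and -0.33 and all plant polysaccharide enzymes between 0.54 and 1.29; relative to all genes both turned on some inducers after normexp correction.

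Among the enzyme groups, the 5 mannan and galactoside enzymes and the 11 xyloglucan enzymes were called on all 10 inducers. Of the mannan list 4 to 5 rose and 0 fell (4 to 5 and 0 adjusted over the list alone), with adjusted p = 0.000474 to 0.0139 (adjusted p = 0.0673 to 0.116 with an estimated correlation). The beta-mannosidase AO090003001410 rose by 1.66 to 2.62, the beta-mannanase AO090010000122 by 0.74 to 1.35 and the alpha-galactosidase AO090010000684 by 6.67 on Turanose and 0.79 to 1.87 elsewhere; the list's median relative to all genes stayed above 0 after both other scalings, but it was called on 1 inducer after normexp correction and 9 after quantile normalization. Of the xyloglucan list 6 to 10 rose and 0 fell (7 to 10 and 0 adjusted over the list alone), with adjusted p = 0.0013 to 0.0064 (adjusted p = 0.219 to 0.255 with an estimated correlation); after normexp correction its median relative to all genes ran from -0.43 to 0.24 and it was called on 4 inducers. Cellulases and beta-glucosidases rose on all inducers but Galactosyl-mannotriose: 10 to 20 of 29 rose and 0 to 1 fell (10 to 20 and 0 to 1 adjusted over the list alone), with adjusted p = 0.00271 to 0.0149 (adjusted p = 0.549 to 0.603 with an estimated correlation) and a relative median of -0.76 to 0.11 after normexp correction, which turned its sign and left 0 calls in camera; quantile normalization left 6. On Galactosyl-mannotriose 10 rose and 0 fell (adjusted p = 0.081).

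The 20 starch and alpha-glucan enzymes were called on Turanose alone, where 9 rose and 1 fell (9 and 2 adjusted over the list alone; adjusted p = 0.0172, or adjusted p = 0.379 with an estimated correlation), and on none after normexp correction. On the others 4 to 11 rose and 0 to 6 fell (4 to 12 and 0 to 6 adjusted over the list alone; adjusted p = 0.119 to 0.8). The alpha-glucosidase AO090001000649 rose by 1.05 to 2.13 and the alpha-amylase AO090103000129 by 1.09 to 1.70 on all inducers, the latter lower than all genes on 4 after normexp correction, whereas the maltase AO090003001209 fell on Sophorose, Turanose, Mannohexaose, Cellohexaose and Xyloglucan with values from -1.46 to -2.15. Of 18 xylan enzymes 3 to 10 rose and 0 to 3 fell (3 to 10 and 0 to 3 adjusted over the list alone), and the list passed on no inducer in camera (adjusted p = 0.217 to 0.567). Of 3 arabinan enzymes 0 to 2 rose, among them the arabinofuranosidase AO090124000023 on D-Xylopentaose (1.57) and Mannohexaose (1.27). Of 2 pectin enzymes 1 to 2 rose. Of 27 enzymes of the fungus's own cell wall 3 to 11 rose and 1 to 3 fell (3 to 11 and 0 to 3 adjusted over the list alone; adjusted p = 0.213 to 0.617), and the chitinase AO090005000815 rose by 1.87 to 2.82 on every inducer.

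The regulator xlnR (AO090012000267), the activator of xylanase and cellulase genes in aspergilli, rose on all 10 inducers by 0.71 to 1.59. The acetate regulator facB (AO090012000525) rose on Sophorose, Turanose, Cellohexaose and Xyloglucan by 1.25 to 1.46, and its values of 0.31 to 0.80 on the other inducers did not pass. Glucokinase (glkA, AO090120000109) and enolase (aspf22, AO090003000055) fell on every inducer, with values from -0.74 to -1.89 and from -0.65 to -1.97. Of the 27 glycolysis genes 4 to 8 rose and 6 to 13 fell (4 to 8 and 6 to 14 adjusted over the list alone). Camera placed the list below other genes on Sophorose, Turanose, Mannohexaose, Cellohexaose and Xyloglucan (adjusted p = 0.0141 to 0.0258; adjusted p = 0.246 to 0.252 with an estimated correlation), with a median of -0.49 and a mean of 0.01 on Mannohexaose; after quantile normalization or normexp correction it passed on 0 inducers, and after normexp correction the median relative to all genes reached 0.20. On the other inducers its adjusted p was 0.169 to 0.354.

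Among 38 genes listed for the citric acid cycle, 4 to 7 rose and 12 to 18 fell (4 to 8 and 13 to 19 adjusted over the list alone). mcsA (AO090009000568), listed by its product name citrate synthase but with the symbol of the methylcitrate synthase of propionate breakdown, rose by 1.29 to 2.03 on every inducer. The citrate synthase cit1 (AO090102000627) and AO090001000484, annotated as an aconitase or homoaconitase, fell, with values from -1.13 to -1.50 and from -0.99 to -1.87. Several members that fell act in leucine or lysine synthesis and are listed by name alone, such as leu2A (AO090005001122), with values from -0.70 to -2.13. The list was called on all 10 inducers (adjusted p = 0.00195 to 0.0154; adjusted p = 0.132 to 0.246 with an estimated correlation), on 6 after quantile normalization and on 5 after normexp correction, where its median relative to all genes ran from -0.67 to 0.04. Of 11 genes of gluconeogenesis, the glyoxylate shunt and acetate use, 4 to 7 rose and 1 to 3 fell (4 to 7 and 1 to 3 adjusted over the list alone). Fructose bisphosphatase (fbp1, AO090003001089) fell on 1,3:1,4-beta-Glucohexaose, Glc-Maltotriosyl-maltotriose, D-Xylopentaose, 1,5-alpha-L-Arabinoheptaose and Galactosyl-mannotriose, with values from -0.62 to -1.56. That list passed on no inducer (adjusted p = 0.0581 to 0.39), on 4 after quantile normalization and on 8 after normexp correction, and on Cellohexaose its median of 0.44 was -0.15 with the slide as a block.

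Cytosolic ribosomal proteins fell on every inducer: 19 to 73 of 82 fell and 0 to 1 rose (18 to 77 and 0 to 1 adjusted over the list alone), and medians ran from -1.08 to -0.33, a sign kept after quantile normalization and normexp correction, although relative to all genes the median reached 0.40 after normexp correction; the list was called on 10 and 8 inducers. The genes rps0 (AO090012000801) and L5 (AO090012000613) gave -1.82 on Cellohexaose and -1.57 on Xyloglucan, and S12 (AO090009000395) gave -1.92 on Mannohexaose. Camera's adjusted p ran from 1.11e-23 on Xyloglucan to 4.35e-06 on Galactosyl-mannotriose (adjusted p = 0.0876 to 0.252 with an estimated correlation). With the slide as a block the median was -0.36 on 1,3:1,4-beta-Glucohexaose and -0.81 on Cellohexaose, and within slide 1 it was -0.36 on 1,3:1,4-beta-Glucohexaose. Against the mean of the other 9 inducers, ribosomal genes were higher on 1,3:1,4-beta-Glucohexaose, Glc-Maltotriosyl-maltotriose, D-Xylopentaose, 1,5-alpha-L-Arabinoheptaose and Galactosyl-mannotriose (6 to 35 rose and 0 fell; adjusted p = 2.27e-15 to 1.28e-05) and lower on the other 5 (13 to 38 fell and 0 to 2 rose; adjusted p = 3.71e-20 to 0.0327), with adjusted p = 0.111 to 0.813 with an estimated correlation. After normexp correction the median relative to all genes turned on 5 of the 10 inducers, among them 1,3:1,4-beta-Glucohexaose, where the list was then called lower (adjusted p = 1.85e-08); after quantile normalization it turned on 0, but 5 of the 10 calls were lost. These sets are those apart on the second principal component.

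Protein folding and secretion genes fell on Sophorose, Turanose, Mannohexaose, Cellohexaose and Xyloglucan, where 8 to 13 of 27 fell and 0 to 2 rose (7 to 13 and 0 to 2 adjusted over the list alone; adjusted p = 1.55e-05 to 0.01; adjusted p = 0.116 to 0.341 with an estimated correlation). The peptidyl-prolyl isomerase AO090001000519 gave -1.58 and calnexin (clxA, AO090009000313), a chaperone of the endoplasmic reticulum, -1.38 on Cellohexaose. The list passed on 2 inducers after quantile normalization, and after normexp correction it passed as higher on 1 and its median relative to all genes ran from -0.43 to 0.89, a turn of its sign. On the other 5 inducers its adjusted p was 0.224 to 0.812. Of 71 heat shock and oxidative stress genes 9 to 23 rose and 13 to 31 fell (10 to 24 and 14 to 33 adjusted over the list alone). That list fell on Sophorose, Turanose, Cellohexaose and Xyloglucan (adjusted p = 0.00228 to 0.00491; adjusted p = 0.246 to 0.25 with an estimated correlation) and passed on no other inducer (adjusted p = 0.0839 to 0.98). After quantile normalization it passed on 0 and after normexp correction as higher on 2, so that its direction turned.

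Calls of single stress genes differed between inducers. The thioredoxin reductase AO090023000260 rose on 1,3:1,4-beta-Glucohexaose, Glc-Maltotriosyl-maltotriose, D-Xylopentaose, 1,5-alpha-L-Arabinoheptaose and Galactosyl-mannotriose by 2.89 to 5.01 and gave values of -0.71 to -0.11, none called, on the others. The catalase-peroxidase AO090010000722 rose on all 10, by 3.29 to 5.88 on these and by 1.65 to 2.76 on the rest. The catalase AO090020000389 rose on the same 5 and on Cellohexaose, with 4.48 (SE 0.54) on 1,3:1,4-beta-Glucohexaose. The chaperone hscA (AO090103000007) fell on every inducer (-0.68 to -1.62). Against the other 9 inducers the stress list was higher on 1,3:1,4-beta-Glucohexaose, D-Xylopentaose, 1,5-alpha-L-Arabinoheptaose and Galactosyl-mannotriose (14 to 19 rose and 0 to 2 fell; adjusted p = 7.11e-08 to 0.000168) and lower on Sophorose, Turanose, Cellohexaose and Xyloglucan (16 to 21 fell and 0 to 4 rose; adjusted p = 8.62e-07 to 0.00623), with adjusted p = 0.111 to 0.321 with an estimated correlation; after normexp correction the relative median turned on 5 of these 8 inducers, and the list was called lower on 1,3:1,4-beta-Glucohexaose (adjusted p = 0.0213). The folding list was higher on the 5 inducers on which AO090023000260 rose (adjusted p = 8.62e-07 to 0.00797). It was lower on Sophorose, Cellohexaose and Xyloglucan (adjusted p = 3.58e-10 to 0.00759), and adjusted p was 0.111 to 0.356 with an estimated correlation. After normexp correction its relative median turned on 1,3:1,4-beta-Glucohexaose, D-Xylopentaose and Cellohexaose, and only the calls on Glc-Maltotriosyl-maltotriose, Galactosyl-mannotriose and Sophorose held. After quantile normalization these and that on 1,5-alpha-L-Arabinoheptaose were lost.

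Secondary metabolism genes were higher than on glucose on 9 inducers: 34 to 72 of 141 rose and 4 to 14 fell (33 to 73 and 4 to 15 adjusted over the list alone), with adjusted p = 0.00277 to 0.0176 (adjusted p = 0.59 to 0.631 with an estimated correlation) and 0.0628 on Turanose; after normexp correction the relative median ran from -0.55 to 0.07, which turned its sign on some and left 1 call. The cytochrome P450 AO090120000106 rose by 5.73 to 6.78 on all 10, and the P450 AO090003000205 fell on all but Mannohexaose, with values from -1.52 to -3.99. Amino acid and nitrogen genes rose on all inducers but Sophorose, Turanose, Cellohexaose and Xyloglucan (36 to 61 of 118 rose and 8 to 17 fell; 37 to 65 and 8 to 17 adjusted over the list alone; adjusted p = 0.00468 to 0.0435; adjusted p = 0.56 to 0.619 with an estimated correlation), with a relative median of -0.21 to 0.12 and so a turned sign on some inducers after normexp correction, when it was called on 1, and 3 called after quantile normalization. On these 4 its adjusted p was 0.123 to 0.259. The amidase AO090003001411 rose by 2.92 to 4.17 and the urea transporter AO090003000854 fell, with values from -1.79 to -3.29, on all 10. Of 51 proteases and peptidases 13 to 18 rose and 4 to 14 fell (13 to 19 and 4 to 14 adjusted over the list alone; adjusted p = 0.0939 to 0.889; called higher on 2 inducers after quantile normalization and 2 after normexp correction); the carboxypeptidase AO090103000026 rose by 1.55 to 2.52 and the dipeptidyl aminopeptidase AO090005000697 fell, with values from -1.09 to -1.74, on every inducer. Of 4 conidiation markers, which could mark spores in the flasks, brlA (AO090005001041) rose on Cellohexaose (0.88) and medA (AO090026000285) on Xyloglucan (0.75). The 1 listed sugar transporter, the nucleotide-sugar carrier gmtA (AO090009000688), fell on Mannohexaose (-0.56), and the list of pentose catabolism matched 0 genes on the array. In all, 89 of 160 list tests against glucose passed in camera, and 0 passed with an estimated correlation.

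Against the mean of the other 9 inducers, further lists moved on single inducers. The carboxypeptidase gene cp6 (AO090012000706) was higher on 1,3:1,4-beta-Glucohexaose (1.52, SE 0.25) and lower on Xyloglucan (-1.57), and the proteases and peptidases as a list were higher on 1,3:1,4-beta-Glucohexaose and Glc-Maltotriosyl-maltotriose (8 to 10 rose and 0 to 2 fell; adjusted p = 0.00173 to 0.00797) and lower on Mannohexaose and Xyloglucan (8 to 11 fell and 1 to 3 rose; adjusted p = 0.00178 to 0.0224), with adjusted p = 0.214 to 0.321 with an estimated correlation and a relative median that turned on 1,3:1,4-beta-Glucohexaose and Xyloglucan after normexp correction; after quantile normalization only the call on 1,3:1,4-beta-Glucohexaose held. Glycolysis genes were higher on 1,3:1,4-beta-Glucohexaose, Glc-Maltotriosyl-maltotriose and Galactosyl-mannotriose (5 to 8 rose and 0 to 3 fell; adjusted p = 0.0192 to 0.0495) and lower on Xyloglucan (7 fell and 1 rose; median 0.06, mean -0.09; adjusted p = 0.0192), with adjusted p = 0.26 to 0.337 with an estimated correlation and a relative median that turned on 1,3:1,4-beta-Glucohexaose after normexp correction; 0 of these 4 calls held after quantile normalization (adjusted p = 0.0790 to 0.254).

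By limma's F test, 6314 of the tested genes (54.8%) differed among the 10 inducers, and 1174 did after normexp correction. From the mean of the other 9, between 676 (1,5-alpha-L-Arabinoheptaose) and 3341 genes (Mannohexaose) differed. After normexp correction 55 (Sophorose) to 406 (1,3:1,4-beta-Glucohexaose) did, with 159 on Mannohexaose. Such counts and values can hold the difference between the sets apart on the second principal component. Cellohexaose and Xyloglucan had 1791 and 1886 genes, but 0 differed between them. With 1 inducer at a time left out of that mean, at least 1 call given below was lost (adjusted p = 0.0543 to 0.0958) for AO090001000544, AO090009000554, AO090166000090, AO090003001341, AO090026000127, AO090005001210, AO090012000267, AO090001000028, AO090038000471, AO090003000174 and AO090038000439.

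1,3:1,4-beta-Glucohexaose, a chain of beta-linked glucose with mixed linkages, gave 8.53 (SE 0.33) for the transporter AO090005000962 against glucose, and AO090010000667, a sterol methyl oxidase of ergosterol synthesis, fell by 5.52 (SE 0.67). The fumarate reductase gene frdA (AO090003000831) and the sterol desaturase AO090005001107 gave -4.82 and -3.86. In all 2240 genes rose and 1451 fell (limma, adjusted p under 0.05); after quantile normalization 1689 rose and 1988 fell, after normexp correction 229 and 361, and without glucose 2 the count was 2401. Set against the other 9 inducers, the transporter AO090026000494 was 1.78 higher (SE 0.27, adjusted p = 6.35e-05), the acyl-CoA dehydrogenase AO090009000596 1.45 and the ketol-acid reductoisomerase AO090701000557, of branched amino acid synthesis, 1.43. Among the enzymes the alpha-amylase AO090023000944 gave 1.31 and cbhC (AO090038000439) -0.55, or 0.45 relative to all genes after normexp correction. The transporter AO090138000118, the cystathionine lyase AO090023000150 and AO090005001107 gave -1.85, -1.83 and -1.82, the last 2 at 0.24 and 0.19 relative to all genes after normexp correction. Here 721 genes were higher and 985 lower; without flask 1, 2 or 3 of the inducer 793, 743 and 1069 genes passed.

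On Glc-Maltotriosyl-maltotriose, built of alpha-linked glucose, AO090010000667 and frdA (AO090003000831) gave -5.15 (SE 0.67) and -4.93 against glucose. A total of 2318 genes rose and 1196 fell (limma); the quantile split was 1691 and 1750 and the normexp split 247 and 378, and 2028 genes passed without glucose 1. Relative to the other 9 inducers the short-chain dehydrogenase AO090023000688 was lower (-2.18, SE 0.17, adjusted p = 9.93e-09), as were the threonine aldolase AO090005000497 (-1.54), the P450 AO090003000205 (-1.71) and phosphoenolpyruvate carboxykinase (acuF, AO090003000174; -0.93), the entry step of gluconeogenesis. The polyketide synthase gene nscA (AO090701000530) was higher by 1.39. Of the amylolytic genes, the alpha-amylase AO090023000944 and the maltase AO090038000471 were higher by 0.90 and 0.77, and the alpha-glucosidase AO090701000639 lower, at -0.97, while the alpha-amylase AO090026000034 gave -0.84, or 0.094 (adjusted p = 0.755) without Turanose in the mean; the starch list as a whole did not pass (adjusted p = 0.574). There were 599 higher and 579 lower genes, and 404 or 392 in total without flask 2 or 3 of the inducer.

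With D-Xylopentaose, a chain of xylose, frdA (AO090003000831), AO090010000667 and the taurine dioxygenase AO090023000200 gave -4.37 (SE 0.57), -4.23 and -3.11 against glucose, while 3296 genes rose and 1383 fell (limma). Quantile normalization gave 1754 rising and 2169 falling genes, and 3098 genes passed without glucose 2. Compared with the other 9 inducers the transporter AO090103000396 was higher by 1.94 (SE 0.22), the taurine dioxygenase AO090005001496 by 1.73 and the alpha-glucosidase AO090005000768 by 1.39. xlnR (AO090012000267) was lower (-0.47, adjusted p = 0.0389), as was the metal-dependent hydrolase AO090005000447 (-1.63). Among xylan genes the 1 called member was AO090005001210 (0.37, or -0.067 with the median of probes), which the list holds as a xylanase or chitin deacetylase (adjusted p of the list = 0.574). Counts were 1020 higher and 476 lower, 969 and 974 after quantile normalization, 162 and 19 after normexp correction, and 592 or 576 in total without flask 1 or 2; without D-Xylopentaose 1 and Xyloglucan 1, an omission chosen after the data were seen, 620 genes passed.

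1,5-alpha-L-Arabinoheptaose raised a pair of genes numbered next to each other above their level on the other 9 inducers: AO090020000390, annotated as a glucose or choline dehydrogenase, by 3.24 (SE 0.37, adjusted p = 3.03e-06) and the catalase AO090020000389 by 2.70 (SE 0.36). Against the other 9 inducers the thioredoxin reductase AO090023000260 gave 3.28 and isocitrate lyase (AO090009000219) 0.57. Against glucose AO090023000260 was highest on D-Xylopentaose (5.01). The alpha-glucuronidase aguA (AO090026000127) and the endoglucanase AO090003001341 were lower (-0.96 and -1.14; 0.05 and 0.17 relative to all genes after normexp correction). With 436 genes higher and 240 lower (limma; 87 and 6 after normexp correction), the count became 1463, 234 and 239 without flask 1, 2 or 3, and 421, 448 and 1183 without Cellohexaose, Sophorose or Galactosyl-mannotriose in the mean. Against glucose frdA (AO090003000831) gave -4.09; 2561 genes rose and 1568 fell, 1797 and 2191 after quantile normalization, with 2717 passing without glucose 1.

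On Galactosyl-mannotriose, a mannose chain bearing galactose, the transporter AO090010000126 was 1.91 above its level on the other 9 inducers (SE 0.15, adjusted p = 9.2e-09), and AO090023000070, a geranylgeranyl pyrophosphate synthase of terpenoid synthesis, 1.74 above it. Plant polysaccharide enzymes were lower: 22 of 88 fell and 2 rose (adjusted p = 0.00093; adjusted p = 0.649 with an estimated correlation), with the beta-glucosidases AO090701000244 and AO090701000274 at -1.24 and -1.03, the xylanase AO090103000326 at -0.70 and the alpha-galactosidase AO090010000684 at -1.03, or -0.42 and not called without Turanose in the mean (adjusted p = 0.0686). Cellulases and starch enzymes were lower as lists too (adjusted p = 0.00668 and 0.0498; adjusted p = 0.695 and 0.494 with an estimated correlation), but after normexp correction the medians of these 3 lists relative to all genes shrank from -0.26, -0.32 and -0.36 to -0.036, -0.041 and -0.17 and none was called (adjusted p = 0.170 to 0.325), nor was the starch list after quantile normalization. The 788 higher and 1211 lower genes (limma) became 876 and 789 after quantile normalization, 127 and 18 after normexp correction and 822 and 506 with the brightest probe, and without flask 1, 2 or 3 the total was 3902, 401 and 418. Against glucose frdA (AO090003000831) gave -3.30; 2309 genes rose and 1621 fell, 1738 and 2191 after quantile normalization, and 2372 passed without glucose 1.

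Sophorose, a disaccharide of glucose, gave 8.57 (SE 0.33) for AO090005000962 and 8.10 for AO090023000688 against glucose, and the hydrolase AO090102000067 was at least 68.7-fold higher, as it was not well above background on glucose. The taurine dioxygenase AO090005001496, which releases sulfite from taurine, gave -5.55 (SE 0.42) and the sulfate exchanger AO090003000798 -4.39. In limma 2837 genes rose and 1788 fell, 2129 and 2289 after quantile normalization and 346 and 433 after normexp correction. The acyl-CoA transferase AO090005000495 was higher than on the other 9 inducers by 2.06 (SE 0.35, adjusted p = 0.000321). The transporter AO090010000126, higher on Galactosyl-mannotriose, was lower here (-1.83), as was malate synthase (AO090009000557; -0.64). The beta-glucosidases AO090009000554 and AO090166000090 gave 0.76 and 0.73. There were 754 higher and 768 lower genes, 9 and 46 after normexp correction, 232 and 797 with the brightest probe, and 696, 939 or 649 in total without flask 1, 2 or 3.

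Turanose, a disaccharide of glucose and fructose, raised the alpha-amylase AO090026000034 above its level on the other 9 inducers by 8.40 (SE 0.15, adjusted p = 7.99e-23), the invertase AO090701000400, which splits sucrose, by 7.44 (SE 0.33), the alpha-galactosidase AO090010000684 by 5.50, the alpha-amylase AO090038000234 by 4.90 and the transporter AO090038000233 by 4.03. The beta-glucosidase AO090701000274 (1.85), the arabinofuranosidase AO090012000298 (0.97) and xlnR (AO090012000267; 0.51, adjusted p = 0.0241) were also higher. The mannan and galactoside list passed (adjusted p = 0.0382, or adjusted p = 0.187 with an estimated correlation), with a mean of 1.07 and a median of -0.12, and AO090010000684 was its 1 called member; the call was lost after normexp correction and quantile normalization (adjusted p = 0.0815 and 0.0918). Counts were 459 higher and 1143 lower (limma), 779 and 836 after quantile normalization, and 685 or 509 in total without flask 1 or 3. Against glucose, where the invertase rose by 8.34 and AO090005001496 gave -5.54, 2337 genes rose and 1689 fell, 281 and 421 after normexp correction.

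**Figure D3:**
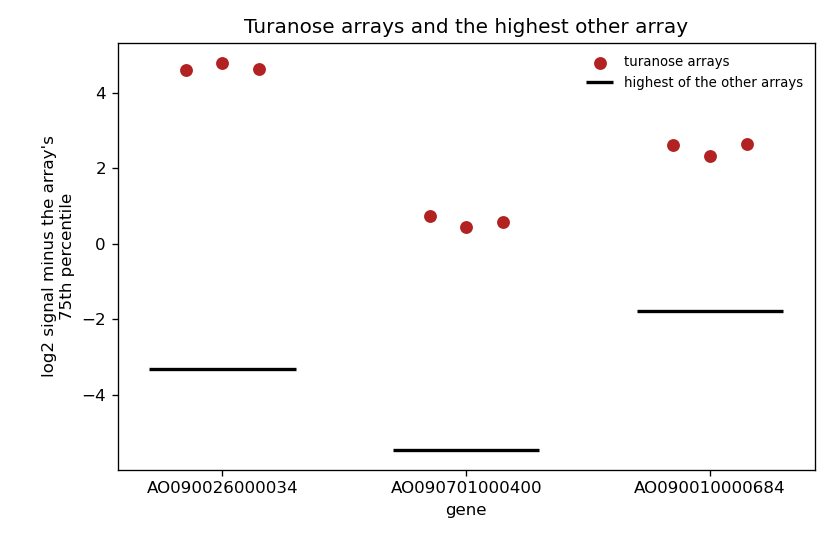
For each of 3 genes (x), points give the 3 Turanose arrays' log2 signal minus the array's 75th percentile (y), and the black line gives the highest of the other arrays. The Turanose arrays lay at 4.61, 4.79 and 4.61 for the alpha-amylase AO090026000034, against a highest other value of -3.30.

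On Mannohexaose, a chain of mannose, the alkaline phosphatase AO090012000725 was 2.55 above its level on the other 9 inducers (SE 0.34), the beta-glucosidase AO090103000127 2.21 (SE 0.59) and the beta-mannosidase AO090003001410, which takes mannose from chain ends, 0.70 (SE 0.12, adjusted p = 0.000181). The beta-xylosidase xlnD (AO090005000986) and the pectate lyase AO090701000321 gave 1.00 and 0.97, and acuF (AO090003000174) 1.30. The alpha-amylases AO090026000034 and AO090038000234 were lower (-1.41 and -1.38, or -0.49 and -0.85 without Turanose in the mean). In limma 1994 genes were higher and 1347 lower, 1758 and 2171 after quantile normalization, and 1651 passed without flask 3. The 3 arrays had the weakest signals of all (75th percentile 255 to 390). Against glucose AO090005000962 gave 8.06 and AO090005001496 -4.76; 4092 genes rose and 2087 fell, 2409 and 3037 after quantile normalization and 470 and 579 after normexp correction.

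On Cellohexaose, an unbranched chain of beta-linked glucose, AO090023000688 gave 7.92 (SE 0.26) against glucose and AO090005001496 -5.33 (SE 0.42); AO090102000067 was at least 53.6-fold higher. There 2954 genes rose and 1813 fell (limma), 2271 and 2341 after quantile normalization and 403 and 887 after normexp correction. Of the cellulase list, the beta-glucosidase AO090001000544 was 0.68 above the other 9 inducers and AO090001000266 -1.10 (adjusted p of the list = 0.531). The transporter AO090026000494, higher on 1,3:1,4-beta-Glucohexaose, gave -1.67 (SE 0.27), the alpha-amylase AO090023000944 -1.40 and gliK (AO090001000030), named for its counterpart in gliotoxin synthesis, -1.61 (SE 0.19). Higher was the P450 AO090012000066 (1.39). Counts were 934 higher and 857 lower, 61 and 292 after normexp correction, and 988, 1095 or 569 in total without flask 1, 2 or 3.

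Xyloglucan, a glucan backbone with xylose side groups, gave 8.24 (SE 0.26) for AO090023000688 and -4.97 for the oxidoreductase AO090001000571 against glucose; 3523 genes rose and 1809 fell (limma), 2229 and 2473 after quantile normalization and 404 and 810 after normexp correction. Set against the other 9 inducers, met16 (AO090020000347), the reductase of activated sulfate, was lower (-1.71, SE 0.18, adjusted p = 8.44e-07), as was the ammonia permease AO090023000411 (-1.52, SE 0.12). Among enzymes, the endoglucanase AO090003001341, the alpha-glucosidase AO090005000767 and the beta-galactosidase AO090023000076 gave 1.00, 1.02 and 0.68 (-0.68 for the first relative to all genes after normexp correction), while the xyloglucan list did not pass (adjusted p = 0.366). Here 1147 genes were higher and 739 lower, 918 and 957 after quantile normalization, 57 and 201 after normexp correction, and 1133, 898 or 1062 in total without flask 1, 2 or 3; without Xyloglucan 1 and D-Xylopentaose 1, 587 were higher and 599 lower.

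Pairs of inducers that differ in a stated structural feature were then compared directly. Those of Cellohexaose and 1,3:1,4-beta-Glucohexaose, 1,3:1,4-beta-Glucohexaose and Sophorose, Mannohexaose and Galactosyl-mannotriose, and Glc-Maltotriosyl-maltotriose and Turanose join the 2 sets that lay apart on the second principal component, where all 25 such pairs differed in 1829 to 3476 genes; the other 4 lie within a set, where 20 pairs differed in 0 to 2452 (median 89). No slide links the inducers of a pair where no fit with the slide as a fixed block is given. The median half-width of the 95% interval of a difference was 0.49 on the log2 scale. Cellohexaose and Sophorose, chains of 6 and 2 glucose units joined by different bonds, differed in few genes. AO090020000390 was higher on Cellohexaose by 2.50 (SE 0.49, adjusted p = 0.0275), and AO090001000038 and AO090001000026, without product names, gave -1.66 and -1.59. In limma 5 genes were higher and 15 lower, and for 8378 (72.7%) the interval lay within a 2-fold change in either direction. The count was 4 (all lower) after normexp correction, 42 after quantile normalization, 47 with the slide as a random block and 3 when only these arrays were fitted. It was 9, 13 or 7 without flask 1, 2 or 3 of Cellohexaose, 12, 13 or 12 without those of Sophorose, and 35 without Turanose 2.

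Xyloglucan and Cellohexaose differ in side groups. No gene passed in limma (0 higher and 0 lower), although 211 had an unadjusted p under 0.05, and for 8636 genes (74.9%) the interval lay within 2-fold; the median size of the difference was 0.14. The count was 0 after normexp correction, with 27 at an unadjusted p under 0.05, and 1 after quantile normalization, with the slide as a random block, or without Xyloglucan 1, Sophorose 2 or Sophorose 3.

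Cellohexaose and 1,3:1,4-beta-Glucohexaose, equal in length but with uniform or mixed bonds, differed in 3058 genes. The short-chain dehydrogenase AO090012000251 was higher on Cellohexaose by 4.02 (SE 0.25, adjusted p = 5.45e-11), and the thioredoxin reductase AO090023000260 was lower (-4.79, SE 0.26), as was AO090011000408, without a product name (-4.01). In limma 1714 genes were higher and 1344 lower, and 50.1% of intervals lay within 2-fold. With the slide as a fixed block 1200 genes passed, and on the slide that held both inducers 1111 were higher and 671 lower. After normexp correction, with the median of all genes at -0.83, 670 were higher and 4343 lower.

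Between 1,3:1,4-beta-Glucohexaose and Sophorose, AO090023000260 was higher on 1,3:1,4-beta-Glucohexaose by 5.07 (SE 0.26) and AO090020000390 by 4.80 (SE 0.49), whereas AO090012000251 and the acyl-CoA transferase AO090005000495 were lower (-4.29 and -3.50). Counts were 1105 higher and 1355 lower (limma), 156 and 128 after normexp correction, 981 and 682 with the brightest probe and 1524 in total without 1,3:1,4-beta-Glucohexaose 2; 53.7% of intervals lay within 2-fold.

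Mannohexaose and Galactosyl-mannotriose, mannose chains without and with a galactose branch and of unequal length, differed in AO090012000901, a sodium and phosphate symporter (3.30, SE 0.84), and AO090012000725, an alkaline phosphatase (3.19, SE 0.46), both higher on Mannohexaose. AO090023000260 and AO090020000390 were lower (-5.03 and -3.96). In limma 1964 genes were higher and 1321 lower, 1726 and 1938 after quantile normalization, 138 and 159 after normexp correction, and 1668 or 1855 in total without Galactosyl-mannotriose 2 or 3; 49.3% of intervals lay within 2-fold. With the slide as a fixed block, which links these inducers only through others, 0 genes passed and 1395 had an unadjusted p under 0.05.

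D-Xylopentaose and 1,5-alpha-L-Arabinoheptaose, both pentose chains, differed in 3 genes, all higher on D-Xylopentaose: the aldo/keto reductase AO090003000859 (1.21, SE 0.16, adjusted p = 0.00123), AO090206000012, with an RCC1 domain (0.73, SE 0.13), and AO090005000698, without a product name (1.36). In limma 1039 genes had an unadjusted p under 0.05, and for 8103 (70.3%) the interval lay within 2-fold. Quantile normalization gave 7 higher and 3 lower genes and the random slide block 6; 0 passed after normexp correction, with the slide as a fixed block or on the slide that held both, where 223, 193 and 347 had an unadjusted p under 0.05. 1 gene passed without 1,3:1,4-beta-Glucohexaose 2, D-Xylopentaose 1 or 2, or 1,5-alpha-L-Arabinoheptaose 2 or 3, 5 without Mannohexaose 1 or 3, 21 without D-Xylopentaose 3 and 62 without 1,5-alpha-L-Arabinoheptaose 1.

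Glc-Maltotriosyl-maltotriose against Turanose, both with alpha-linked glucose and the latter with fructose, gave -8.32 (SE 0.20) for the alpha-amylase AO090026000034, -7.33 (SE 0.44) for the invertase AO090701000400 and -5.45 for the alpha-galactosidase AO090010000684, all higher on Turanose. AO090038000148, without a product name, was higher on Glc-Maltotriosyl-maltotriose (3.91, SE 0.19). In limma 1188 genes were higher and 738 lower, 817 in total when only these arrays were fitted and 221 after normexp correction, and 1272, 1192 or 1132 passed without Glc-Maltotriosyl-maltotriose 3, Turanose 1 or Turanose 3. For 55.7% of genes the interval lay within 2-fold.

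Cellohexaose and Mannohexaose, chains of 6 glucose or 6 mannose units, differed in AO090020000390, higher on Cellohexaose by 2.23 (SE 0.49), and in the importin AO090005001133 (1.80, SE 0.39), a nuclear transport receptor. In limma 1056 genes were higher and 1396 lower, 1766 and 1290 after quantile normalization, 55 and 220 after normexp correction, and 974, 844 or 1285 in total without Cellohexaose 1, Cellohexaose 3 or Mannohexaose 3. Intervals lay within 2-fold for 56.6% of genes.

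**Figure D4:**
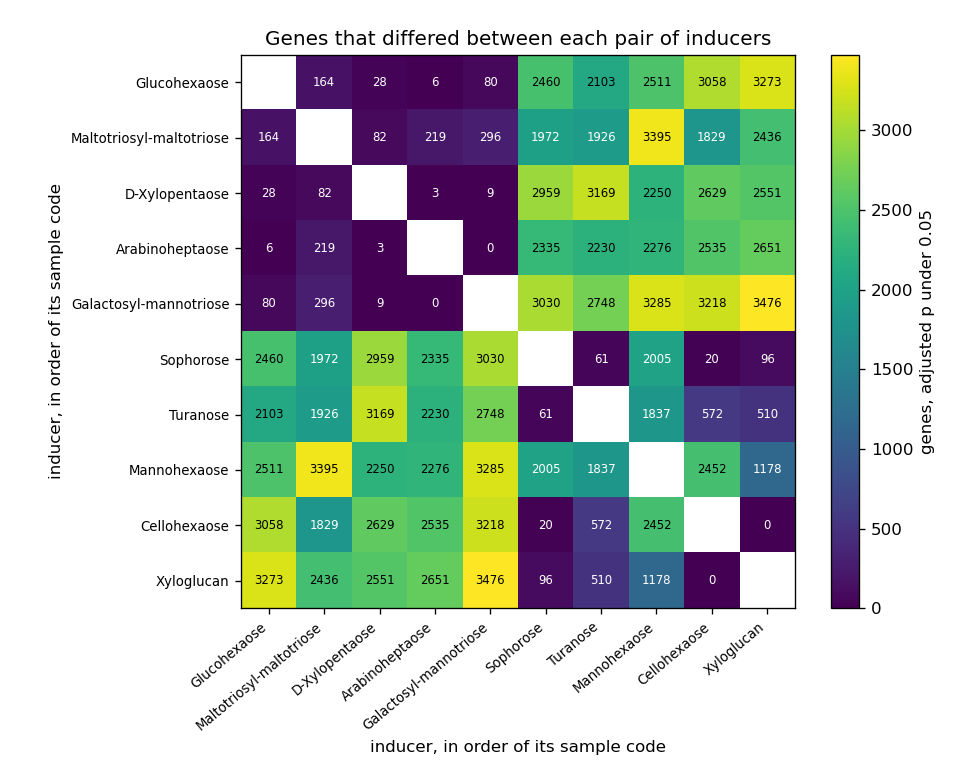
Each cell gives the number of genes that differed (limma, adjusted p under 0.05) between the inducer of its row (y) and that of its column (x), both in the order of the study's sample codes. Xyloglucan and Cellohexaose differed in 0 genes, 1,5-alpha-L-Arabinoheptaose and Galactosyl-mannotriose in 0, and Xyloglucan and Galactosyl-mannotriose in 3476.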

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

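All tests of this part were chosen after the fits had been seen. Among the genes with a product name that the rule takes against glucose and all other genes named in the text, 12 were called in opposite directions against glucose on different inducers, and the difference between the 2 inducers that lay farthest apart was tested in limma with n = 3 on each side. As that pair was picked for its distance, the p-values below are too small.

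The alpha-amylase AO090026000034 rose on Turanose (8.29) and fell on Mannohexaose (-0.54), a difference of 8.83 (SE 0.20, adjusted p = 2.56e-20). The alpha-amylase AO090038000234 rose on Turanose alone (3.84) and fell on 7 inducers, most on Mannohexaose (-1.81), a difference of 5.65 (SE 0.28, adjusted p = 3.54e-13). The glucose or choline dehydrogenase AO090020000390 rose on 6 inducers, most on 1,5-alpha-L-Arabinoheptaose (4.42), and fell on Turanose (-1.54), a difference of 5.97 (SE 0.49, adjusted p = 4.56e-09), and the transporter AO090010000126 rose on 3 and fell on 5, from 1.02 on Galactosyl-mannotriose to -2.35 on Sophorose (difference 3.37, SE 0.20). In the run of genes with gliK (AO090001000030), the differences were 2.75 (SE 0.26) for gliK, 2.48 (SE 0.18) for gliI (AO090001000033), 2.43 for AO090001000038, 2.01 for AO090001000026 and 1.77 for the P450 AO090001000028, each lowest on Cellohexaose and highest on Galactosyl-mannotriose or 1,5-alpha-L-Arabinoheptaose. The catalase AO090120000068 rose on 4 inducers and fell on 4, from 1.67 on D-Xylopentaose to -1.65 on Turanose, a difference of 3.32 (SE 0.33, adjusted p = 7.39e-08). The carboxypeptidase AO090023000382 rose on Glc-Maltotriosyl-maltotriose (0.66) and fell on Xyloglucan (-1.27), a difference of 1.93 (SE 0.22, adjusted p = 1.07e-06). The chitin synthase AO090026000212, of the fungus's cell wall, rose on D-Xylopentaose (0.63) and fell on Turanose (-0.55), a difference of 1.18 (SE 0.15, adjusted p = 5.48e-06).

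On the 3 Turanose arrays (both slides), the alpha-amylase AO090026000034, the invertase AO090701000400 and the alpha-galactosidase AO090010000684 lay at least 4.10 above any other array. This argues against a single faulty array or slide as the source. Each of their probes rose by at least 5.13 over the other inducers, so that no single probe gave the rise. The genes were picked for large rises on every array, so neither test is independent. Binding of all probes to another transcript, a response to the sugar and one to a trace of another sugar stay open and untested.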

How the results depend on the processing

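The fits within 1 slide, other means of the inducers and the omission of Xyloglucan 1 and D-Xylopentaose 1 were chosen after the data were seen; the other settings were planned. Of 485 values of named genes, 464 kept direction and call after quantile normalization, 485 with the slide as a random block, 485 without the filter on dim genes, 484 with outlier spots kept, 482 with a trended and robust prior, 447 when only the groups compared were fitted, 438 with the median of probes, 431 with the brightest probe and 222 under normexp correction. In the deposited tables of the authors a count of 208 of 368 did, and with 1 array left out 15351 of 15520. For changes in all parts below the cause was not tested, except where fewer arrays were fitted or a fold limit was set. Dim genes limit these data, most of all on Mannohexaose. Without Xyloglucan 1 and D-Xylopentaose 1 the counts against the other inducers were 1186 for Xyloglucan and 620 for D-Xylopentaose, 1 gene passed between Xyloglucan and Cellohexaose and 1 between D-Xylopentaose and 1,5-alpha-L-Arabinoheptaose, and 474 of the 485 values of named genes kept their call. With 1 inducer at a time left out of the mean of the others, 806 of 846 values kept direction and call, AO090026000034 turned to 0.094 on Glc-Maltotriosyl-maltotriose without Turanose, and 1,5-alpha-L-Arabinoheptaose had 421, 448 and 1183 genes without Cellohexaose, Sophorose and Galactosyl-mannotriose.

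Under normexp correction the counts against glucose were 590 (1,3:1,4-beta-Glucohexaose), 625 (Glc-Maltotriosyl-maltotriose), 360 (D-Xylopentaose), 454 (1,5-alpha-L-Arabinoheptaose), 468 (Galactosyl-mannotriose), 779 (Sophorose), 702 (Turanose), 1049 (Mannohexaose), 1290 (Cellohexaose) and 1214 (Xyloglucan), and against the other inducers 406, 151, 181, 93, 145, 55, 124, 159, 353 and 258 in the same order. Pairs gave 5013 (Cellohexaose and 1,3:1,4-beta-Glucohexaose), 284 (1,3:1,4-beta-Glucohexaose and Sophorose), 275 (Cellohexaose and Mannohexaose), 4 (Cellohexaose and Sophorose), 221 (Glc-Maltotriosyl-maltotriose and Turanose), 297 (Mannohexaose and Galactosyl-mannotriose) and 0 in limma (D-Xylopentaose and 1,5-alpha-L-Arabinoheptaose, with 223 at an unadjusted p under 0.05). The F test gave 1174 genes, the overlap of all inducers 116 and the gene lists 58 calls against 128, 38 of them shared. With an estimated correlation 0 of the list calls held in camera.

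Under normexp correction 56 values of single genes changed sign, but they hold the shift of all genes, and relative to the median of all genes 23 turned: those of AO090011000673, those of AO090038000439 and AO090103000129 on Cellohexaose, Glc-Maltotriosyl-maltotriose, Turanose and Xyloglucan, that of AO090038000439 on Galactosyl-mannotriose, and those against the other inducers but for AO090138000118 and AO090023000076. As fitted, the values on Cellohexaose were -0.026 for AO090001000649, -0.46 for AO090003001411, -0.29 for AO090005001041, -0.25 for AO090010000122, -0.31 for AO090010000684, -1.86 for AO090011000673, -0.80 for AO090038000223, -1.33 for AO090038000439 and -0.91 for AO090103000129. On Glc-Maltotriosyl-maltotriose they were -0.046 for AO090003001410, -0.76 for AO090003001411, -0.64 for AO090010000122, -0.41 for AO090010000684, -1.87 for AO090011000673, -0.75 for AO090038000223, -1.51 for AO090038000439 and -1.08 for AO090103000129. For Galactosyl-mannotriose the values were -0.35 for AO090003001411, -0.010 for AO090010000122, -0.27 for AO090010000684, -0.81 for AO090011000673, -0.23 for AO090038000223, -0.64 for AO090038000439 and -0.52 for AO090103000129. With Turanose they stood at -0.052 for AO090001000649, -0.42 for AO090003001411, -0.30 for AO090010000122, -1.12 for AO090011000673, -0.47 for AO090038000223, -1.03 for AO090038000439 and -0.65 for AO090103000129. Xyloglucan gave -0.29 for AO090003001411, -0.19 for AO090010000122, -0.38 for AO090010000684, -1.62 for AO090011000673, -0.57 for AO090038000223, -1.11 for AO090038000439 and -0.93 for AO090103000129. 1,5-alpha-L-Arabinoheptaose gave -0.073 for AO090003001411, -0.13 for AO090010000684, -0.50 for AO090011000673, -0.30 for AO090038000439 and -0.28 for AO090103000129. Sophorose gave -0.48 for AO090011000673, -0.32 for AO090038000439 and -0.17 for AO090103000129. D-Xylopentaose gave -0.18 for AO090011000673. Against the other inducers the sign turned to 0.73 for AO090005001107, 0.78 for AO090023000150, 1.00 for AO090038000439 and 0.44 for AO090138000118 on 1,3:1,4-beta-Glucohexaose, to 0.32 for AO090003001341 and 0.20 for AO090026000127 on 1,5-alpha-L-Arabinoheptaose, and to -1.04 for AO090003001341 and -0.12 for AO090023000076 on Xyloglucan. Between Cellohexaose and Mannohexaose AO090020000390 gave -0.54. Relative to the median alone, AO090003000055, AO090003001089, AO090103000007 and AO090120000109 on Glc-Maltotriosyl-maltotriose and AO090124000023 on Mannohexaose turned against glucose, to 0.27, 0.01, 0.28, 0.20 and -0.03. With the median of probes AO090005001210 turned to -0.067 on D-Xylopentaose against the other inducers.

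At least 2-fold changes, a limit that by construction lowers the counts, were found in 1887 (1,3:1,4-beta-Glucohexaose), 1813 (Glc-Maltotriosyl-maltotriose), 2685 (D-Xylopentaose), 2206 (1,5-alpha-L-Arabinoheptaose), 2077 (Galactosyl-mannotriose), 2597 (Sophorose), 2205 (Turanose), 3922 (Mannohexaose), 2753 (Cellohexaose) and 3220 (Xyloglucan) genes against glucose, and in 854 on all inducers. By gene, the authors' deposited tables gave 614, 184, 252, 442, 253, 1155, 502, 612, 1240 and 1067 in the same order.

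The brightest probe gave 1033 (1,3:1,4-beta-Glucohexaose), 1328 (Galactosyl-mannotriose), 1005 (Cellohexaose) and 1044 (Xyloglucan) genes against the other inducers, 5 between Cellohexaose and Sophorose and 0 in limma between D-Xylopentaose and 1,5-alpha-L-Arabinoheptaose (1055 at an unadjusted p under 0.05). The median of probes gave 1095 (1,3:1,4-beta-Glucohexaose), 450 (1,5-alpha-L-Arabinoheptaose), 1233 (Galactosyl-mannotriose), 953 (Sophorose), 1033 (Turanose), 1047 (Cellohexaose) and 1071 (Xyloglucan), 11 between Cellohexaose and Sophorose and 1 between Xyloglucan and Cellohexaose. Quantile normalization gave 42, 1 and 10 genes for Cellohexaose and Sophorose, Xyloglucan and Cellohexaose, and D-Xylopentaose and 1,5-alpha-L-Arabinoheptaose; the slide as a random block gave 47, 1 and 6. The first 2 of these pairs had 36 and 1 with a trended and robust prior and 32 and 1 when every array had to be well above background. With only the groups compared, which leaves fewer arrays to estimate the spread, 2106 (Glc-Maltotriosyl-maltotriose), 1680 (D-Xylopentaose) and 2012 (Galactosyl-mannotriose) genes passed against glucose, 3 between Cellohexaose and Sophorose, 1342 between Mannohexaose and Galactosyl-mannotriose, 817 between Glc-Maltotriosyl-maltotriose and Turanose and 0 in limma between D-Xylopentaose and 1,5-alpha-L-Arabinoheptaose (545 at an unadjusted p under 0.05). With the slide as a fixed block 2995 passed for Cellohexaose against glucose, 1200 between Cellohexaose and 1,3:1,4-beta-Glucohexaose, and 0 in limma between D-Xylopentaose and 1,5-alpha-L-Arabinoheptaose and between Mannohexaose and Galactosyl-mannotriose (193 and 1395 at an unadjusted p under 0.05). Within the slide holding both, 1782 passed between Cellohexaose and 1,3:1,4-beta-Glucohexaose and 0 in limma between D-Xylopentaose and 1,5-alpha-L-Arabinoheptaose (347 at an unadjusted p under 0.05).

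With the flask number as a replicate block, 1 gene passed between D-Xylopentaose and 1,5-alpha-L-Arabinoheptaose and no other count moved by over 1.5 times. The numbers do not pair the flasks: correlations of arrays with the same number, after removal of group means, ran from -0.70 to 0.84, and exceeded 0.1 in 26 of 55, 21 of 55 and 18 of 45 pairs for numbers 1, 2 and 3.

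Leaving out 1 array, which leaves fewer samples, gave against glucose 2401 to 3970 genes (1,3:1,4-beta-Glucohexaose), 2028 to 3787 (Glc-Maltotriosyl-maltotriose), 3098 to 5468 (D-Xylopentaose), 2717 to 4418 (1,5-alpha-L-Arabinoheptaose), 2372 to 4538 (Galactosyl-mannotriose), 3445 to 4848 (Sophorose), 2968 to 4257 (Turanose), 4144 to 6500 (Mannohexaose), 3447 to 5001 (Cellohexaose) and 4080 to 5562 (Xyloglucan). Against the other inducers the ranges were 743 to 1875, 392 to 1386, 576 to 2080, 234 to 1463, 401 to 3902, 649 to 1957, 509 to 2283, 1651 to 3988, 569 to 2182 and 898 to 2406 in that order. The pairs gave 7 to 35 (Cellohexaose and Sophorose), 2131 to 3341 (Cellohexaose and 1,3:1,4-beta-Glucohexaose), 1524 to 2754 (1,3:1,4-beta-Glucohexaose and Sophorose), 1668 to 4581 (Mannohexaose and Galactosyl-mannotriose), 0 to 1 in limma (Xyloglucan and Cellohexaose), 1 to 62 (D-Xylopentaose and 1,5-alpha-L-Arabinoheptaose), 1132 to 2303 (Glc-Maltotriosyl-maltotriose and Turanose) and 844 to 2890 (Cellohexaose and Mannohexaose). The F test gave 5623 to 7366 genes and the overlap of all inducers 1067 to 1675. Gene lists were not tested again with arrays left out.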

Other observations

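The genes of the next paragraph and all tests of explanations below were chosen after the values were seen; the comparisons with other groupings of the arrays were planned.

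Several runs of genes that neighbour each other in the RefSeq gene table moved together between inducers. From AO090001000024 to AO090001000038, a run that holds gliK (AO090001000030) and gliI (AO090001000033), both named for counterparts in gliotoxin synthesis, the P450 AO090001000028 and the exporter AO090001000032, all measured genes were called lower on Cellohexaose than on the other 9 inducers (gliK -1.61, gliI -1.48, the P450 -1.36) and most were called higher on Galactosyl-mannotriose (gliK 1.44, gliI 1.27, the P450 0.61), while AO090001000023 beside the run gave -0.03 and -0.01, neither called. On 1,5-alpha-L-Arabinoheptaose all were called higher and on Xyloglucan most lower. Next to each other, the alpha-amylase AO090038000234 and the transporter AO090038000233 were higher on Turanose (4.90 and 4.03), and their neighbours AO090038000235 and AO090038000232 gave 0.34 and -0.38, neither called. A further run, around the P450 AO090011000411, followed no single inducer. It was higher on the 5 inducers on which AO090023000260 rose (1.98 to 2.35, with 2.26 to 2.78 for AO090011000408). On the other 5 it was lower (-1.85 to -2.40 and -2.00 to -2.69).

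In the study's sample codes the 5 inducers on which that run was higher come first, and every pair of 1 of these with 1 of the other 5 differed in 1829 to 3476 genes (median 2551, 25 pairs), against 0 to 2452 (median 89, 20 pairs) for pairs on 1 side. This division was noticed in the data, and no test between the 2 sets of inducers is reported. Slide effects are argued against by the genes called between Turanose and 1,5-alpha-L-Arabinoheptaose: 70.8% kept their direction within all 3 slides that hold inducers of both sides, where 12.5% would by chance. Scaling is argued against by the median of 2943 genes across the codes after quantile normalization against 135.5 on 1 side, and the sugars' structures stay open as an untested explanation. Use of the 2 batch cultivations in code order may account for it, but the labels tie no flask to either, and 3 pairs on 1 side, all with Mannohexaose, reach 1829 genes, so that it cannot be told apart from the inducers.

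Xyloglucan 1 and D-Xylopentaose 1 had the highest shares of probes well above background. A raised signal of dim spots may account for their distance from their groups: the median deviation from the group's other arrays was 1.29 in the dimmest and 0.00 in the brightest of 3 equal parts of the genes on Xyloglucan 1, and 1.15 and -0.01 on D-Xylopentaose 1, so that the smaller difference was 1.17. No biological explanation was tested.

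Among 100 groupings of the 30 inducer arrays, the real one gave 6314 genes that differed and the highest other 2023, so that 1 of 100 gave as many and chance is excluded. Against the other inducers, and with the same limit, 1 of 100 was as high for 1,3:1,4-beta-Glucohexaose (1706, highest other 4), Cellohexaose (1791, 1), Xyloglucan (1886, 8), Glc-Maltotriosyl-maltotriose (1178, 3), D-Xylopentaose (1496, 613), Galactosyl-mannotriose (1999, 38), Turanose (1602, 75) and Mannohexaose (3341, 46). For 1,5-alpha-L-Arabinoheptaose (676) and Sophorose (1522), 2 of 100 gave as many, with 2852 and 2181 genes in the highest other. A grouping with several times the real count, as for 1,5-alpha-L-Arabinoheptaose, points to a structure of the samples. The 10 splits of 3 against 3 arrays are too few to exclude chance in the pairs; the real and highest other counts were 20 and 0 (Cellohexaose and Sophorose), 3058 and 0 (Cellohexaose and 1,3:1,4-beta-Glucohexaose), 2460 and 0 (1,3:1,4-beta-Glucohexaose and Sophorose), 3285 and 663 (Mannohexaose and Galactosyl-mannotriose), 0 and 0 (Xyloglucan and Cellohexaose, with all 10 splits at 0), 1926 and 4 (Glc-Maltotriosyl-maltotriose and Turanose) and 2452 and 1 (Cellohexaose and Mannohexaose). For D-Xylopentaose and 1,5-alpha-L-Arabinoheptaose they were 3 and 667, 2 of 10 splits reached the real count, and the higher split, of D-Xylopentaose 1 and 2 with 1,5-alpha-L-Arabinoheptaose 1 against the rest, points to a structure of the samples.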
